A study of Enterococcus faecalis with 20 samples.

How the data were processed

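Expression was measured by strand-specific RNA sequencing in 20 libraries of Enterococcus faecalis strain 12030. Per the labels, cultures in brain heart infusion at an optical density of about 0.6 received 12 cm2 of steel mesh in 30 ml and were shaken at 150 rpm and 37 °C. The mesh carried an AGXX coating, a silver (Ag) coating or no coating (V2A), and each mesh gave 1 library at 3, 6, 12, 24, 60 or 90 min. Without a mesh, 2 untreated libraries were made at 0 min. Ribosomal and transfer RNA were depleted, and the RNA was fragmented with RNase III before sequencing on an Ion Proton instrument.

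The authors deposited 1 table of FPKM (fragments per kilobase of gene, scaled to the size of the library) for 3073 protein-coding genes, with 1 column per library. Whether a library pools several cultures is not given in the sources used here. The submitters' processing notes name Bowtie2 2.2.3, SAMtools 1.2-207, Cufflinks and edgeR. Their roles, and any filter on the values, are not given in the sources used here. The deposited annotation was made with RAST on 134 contigs holding 2895603 bp. It gives the start and end of each gene in base positions, with product names and no gene symbols, and 778 of the genes have a hypothetical product. Genes are named here by their identifiers, written with _ for each point of the original, with the product as annotated. All 3073 genes matched the annotation, and 3070 of them started at a start codon. The deposited protein sequences and a second copy of the annotation were not used here.

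Depth was inferred from the values, since no read counts were used. In each library the product of FPKM and gene length took 1 exact smallest value, shared by 6 to 86 genes within a tolerance of 0.1%, and that value was read as 1 read. The depths implied ran from 1700000 to 7950000 reads. They were 3430000 and 1700000 in the untreated libraries, 1720000 to 3510000 with V2A, 1940000 to 4550000 with Ag and 2460000 to 7950000 with AGXX. At all 6 times the AGXX library was deeper than the V2A library. Between 21 and 243 genes per library stood at 0. Among values under 10 reads, 7.1% to 17.5% were whole reads within 0.02, so whole counts were not recovered and no counting intervals are given. Genes under 300 bp numbered 541, the shortest of 114 bp, and their values rest on few reads. A near-identical copy (at least 95% identity over at least 50% of the length by BLAST+ 2.17.0) was found for 52 genes, whose reads may be split or shared.

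Values were analysed as log2(FPKM + 1). The 2534 genes with a mean of at least 5 FPKM over the 20 libraries were tested with limma 3.58.1 in R 4.3.3 (moderated test with an intensity trend), and adjusted p-values follow Benjamini and Hochberg with a threshold of 0.05. AGXX, Ag and V2A were compared in 1 fit of the 18 mesh libraries with the 6 times as a factor, which left 10 residual degrees of freedom. The 6 libraries of a mesh were treated as independent, and whether they came from separate cultures was not established here. No mesh and time had a second library. Each p-value of that fit therefore measures the mesh difference against 1 residual spread per gene, taken over all 18 libraries and moderated. A comparison of AGXX and V2A thus rests also on how Ag varied over the 6 times. Errors are standard errors (SE) of the same fit with n = 6 libraries per mesh. A slope fit tested whether a mesh difference changed per doubling of exposure time (8 residual degrees of freedom). Time on V2A was tested as a slope on log2(minutes) in its 6 libraries (4 residual degrees of freedom). Each mesh was compared with the 2 untreated libraries in a fit of all 20 libraries (16 residual degrees of freedom), where mesh and incubation time cannot be told apart. Genes at least 4-fold apart were counted between library pairs of the same time, without a test.

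Before the data were examined, 22 gene lists were fixed as patterns over product names, together with the comparisons, thresholds, alternatives and the rule for named genes. The list of stable RNA genes matched only proteins and was not tested, which left 21. After the results had been seen, members matched by chance letters or by other functions were removed from 9 of the tested lists. The lists without that removal are among the alternatives. Lists were tested with camera at a preset correlation of 0.01, and with camera at an estimated correlation and fry beside it. Camera compares a list with all other genes, whereas fry tests the list alone. Adjusted p-values of lists run over the 21 lists of a comparison. Counts "adjusted over the list alone" come from limma p-values adjusted within the list.

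Named genes followed this rule. For the 3 mesh comparisons they were the 12 genes with the largest change among those called with the same sign at all 6 times and a named product, up to 3 members with the smallest p of each list called by camera, and every member of the copper list. For the slope, time and untreated comparisons they were the 5 genes that rose and the 5 that fell most among those called with a named product. Genes outside the rule are said to be so.

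The test was run on simulated data with the size and per-gene spread of the tested table. Noise was normal and independent, drawn from the additive model that was then fitted, so the share of false calls is largely met by construction. Correlated genes and libraries of unequal spread were not simulated. With 200 changed genes and 5 draws, the mesh test recovered 34.4% of genes changed by a log2 of 1, 83.2% at 2, 90.4% at 3 and 98% at 4, and 4.5% of calls were false. The slope test recovered 21.6% at a log2 of 0.5 per doubling, 75.6% at 1 and 87.6% at 1.5.

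Alternatives covered the pseudocount (0.1 and 10), the filter on low values (none, or 20 FPKM), median-ratio scaling and quantile normalization between libraries, robust moderation, a threshold of 0.01, the time term, fits of the 12 libraries of 2 meshes, and leaving out each time or library. Chosen after seeing the data were a filter of at least 300 bp and 20 reads on average, library weights, log2 depth as a covariate, and thinning of all libraries to the depth of the shallowest. In the assembly, 200 bp upstream and 10 bp inside each gene were searched for a copper-repressor site and a zinc-repressor site in 3053 genes. Scripts used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.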

Results

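The series asked how Enterococcus faecalis 12030, a gut bacterium and hospital pathogen, alters its gene expression under metal stress from an antimicrobial coating. AGXX is a coating of silver and ruthenium, Ag is plain silver, and V2A is the stainless steel that carries both. Each mesh was sampled once at each of 6 times. Differences are therefore means over the 6 times with the SE of the fit (n = 6 libraries per mesh), given on the log2 scale unless a fold is stated.

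With AGXX, the 3 genes of a copper export unit were 26.4- to 59.6-fold higher than with V2A, and higher at all 6 times. EF_peg_3041, annotated as the negative regulator of a copper transport operon, was higher by 5.90 ± 0.83 (adjusted p = 0.00432). EF_peg_3040, a copper-translocating P-type ATPase that pumps copper across the membrane, was higher by 5.40 ± 0.66 (adjusted p = 0.00249). EF_peg_3039, a copper chaperone, which carries copper ions inside the cell, was higher by 4.72 ± 0.60 (adjusted p = 0.00249). The 3 genes lie side by side on the minus strand of contig 95, from 35 to 241 (EF_peg_3039), 263 to 2749 (EF_peg_3040) and 2765 to 3205 (EF_peg_3041). The ATPase gene measured 10.9 and 14.3 FPKM in the untreated libraries, 10.7 to 30.4 FPKM with V2A and 285 to 2284 FPKM with AGXX. Of the 8 tested members of the copper list, 4 rose, and 5 did when adjusted over the list alone, with a median of 1.38 and 7 positive (6 after median-ratio scaling). The list was called by camera (adjusted p = 1.03e-06), but adjusted p = 0.124 with an estimated correlation. The fourth riser was EF_peg_1929, an ATPase annotated for lead, cadmium, zinc, mercury and copper, higher by 1.53 ± 0.23 at all 6 times (adjusted p = 0.00806). A similarly annotated ATPase, EF_peg_2342, had 1.24 ± 0.39 (adjusted p = 0.161). The remaining members were EF_peg_1569 at 0.16 ± 0.31, EF_peg_1570 at 0.04 ± 0.38 and EF_peg_1517, the copper homeostasis protein cutC, at -0.04 ± 0.20.

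**Figure D1:**
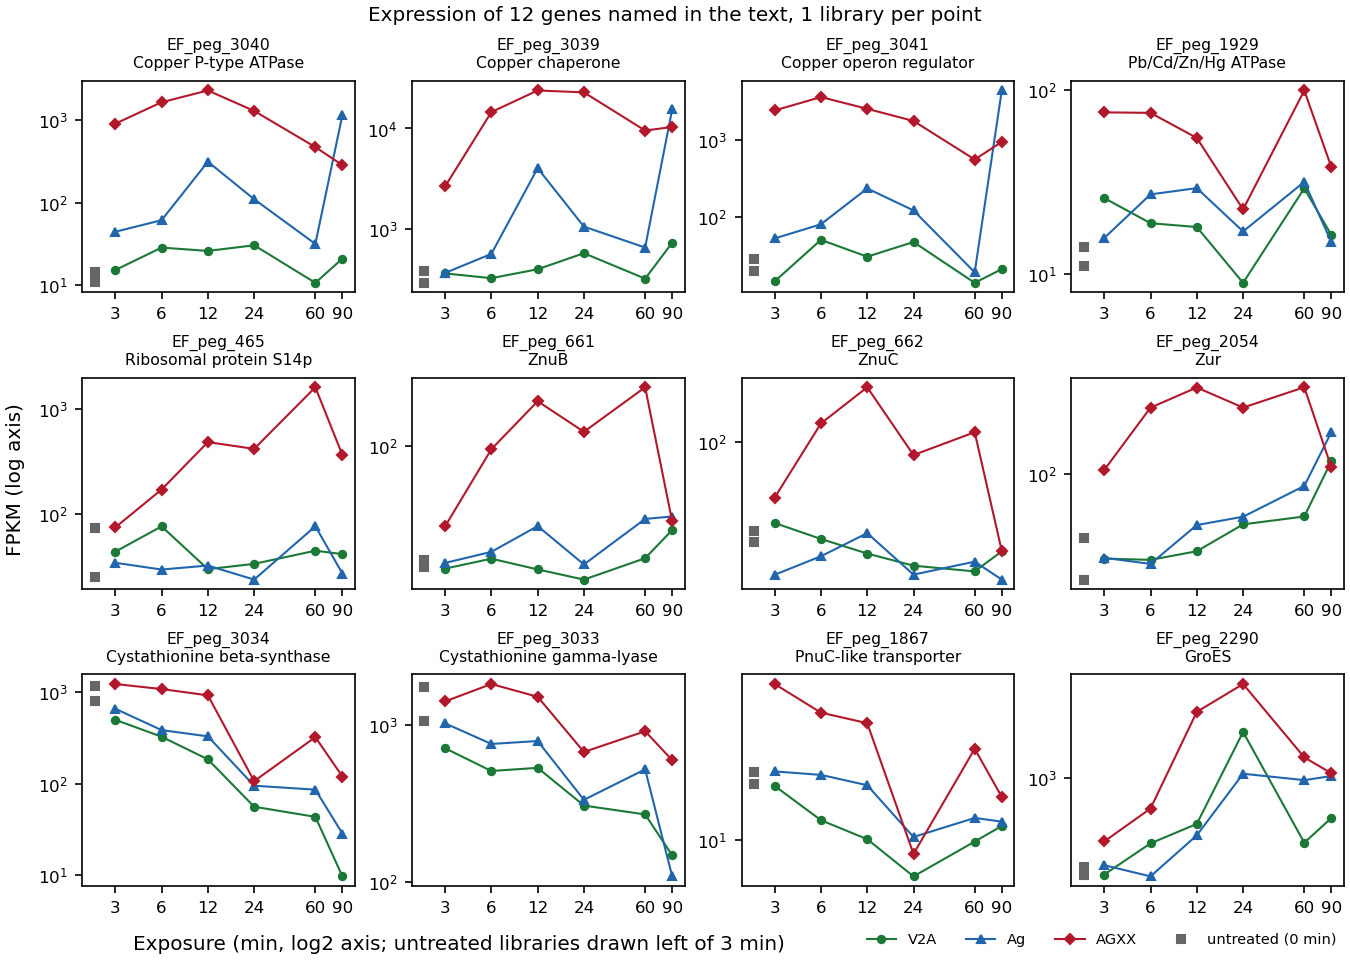
FPKM (log axis) against exposure time (min, log2 axis) for 12 genes, with 1 point per library, lines by mesh and the 2 untreated libraries as squares. The copper ATPase EF_peg_3040 lies between 285 and 2284 FPKM with AGXX and between 10.7 and 30.4 FPKM with V2A.

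The zinc importer genes EF_peg_661 and EF_peg_662 on contig 22, for the permease ZnuB and the ATP-binding protein ZnuC, were higher with AGXX than with V2A by 2.37 ± 0.43 (adjusted p = 0.0238) and 1.97 ± 0.39 (adjusted p = 0.0367). The third gene of the importer, EF_peg_663 for the binding protein ZnuA, outside the rule for named genes, did not pass (1.98 ± 0.56, adjusted p = 0.122). EF_peg_465, a small-subunit ribosomal protein S14p on contig 2 (52034 to 52303, plus strand), was higher by 2.96 ± 0.47 (adjusted p = 0.0088). EF_peg_2054, the zinc uptake regulator Zur, was higher by 2.77 ± 0.51 (adjusted p = 0.0238). It also lay outside the rule, with the same sign at 5 of 6 times. These means did not hold at every time. At 90 min the difference was 0.19 for EF_peg_661 and 0.01 for EF_peg_662, but still 3.11 for EF_peg_465. EF_peg_663 then measured 10.1 FPKM with AGXX and 20.8 FPKM with V2A, and EF_peg_2054 113.6 and 127.1 FPKM. Of 42 members tested in the list of other metal transporters, 4 rose, and 6 did when adjusted over the list alone. That list had a median of -0.13, a mean of 0.12 and a negative camera direction (adjusted p = 0.889), while fry's test for changes in either direction gave an adjusted p of 0.000847.

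**Figure D2:**
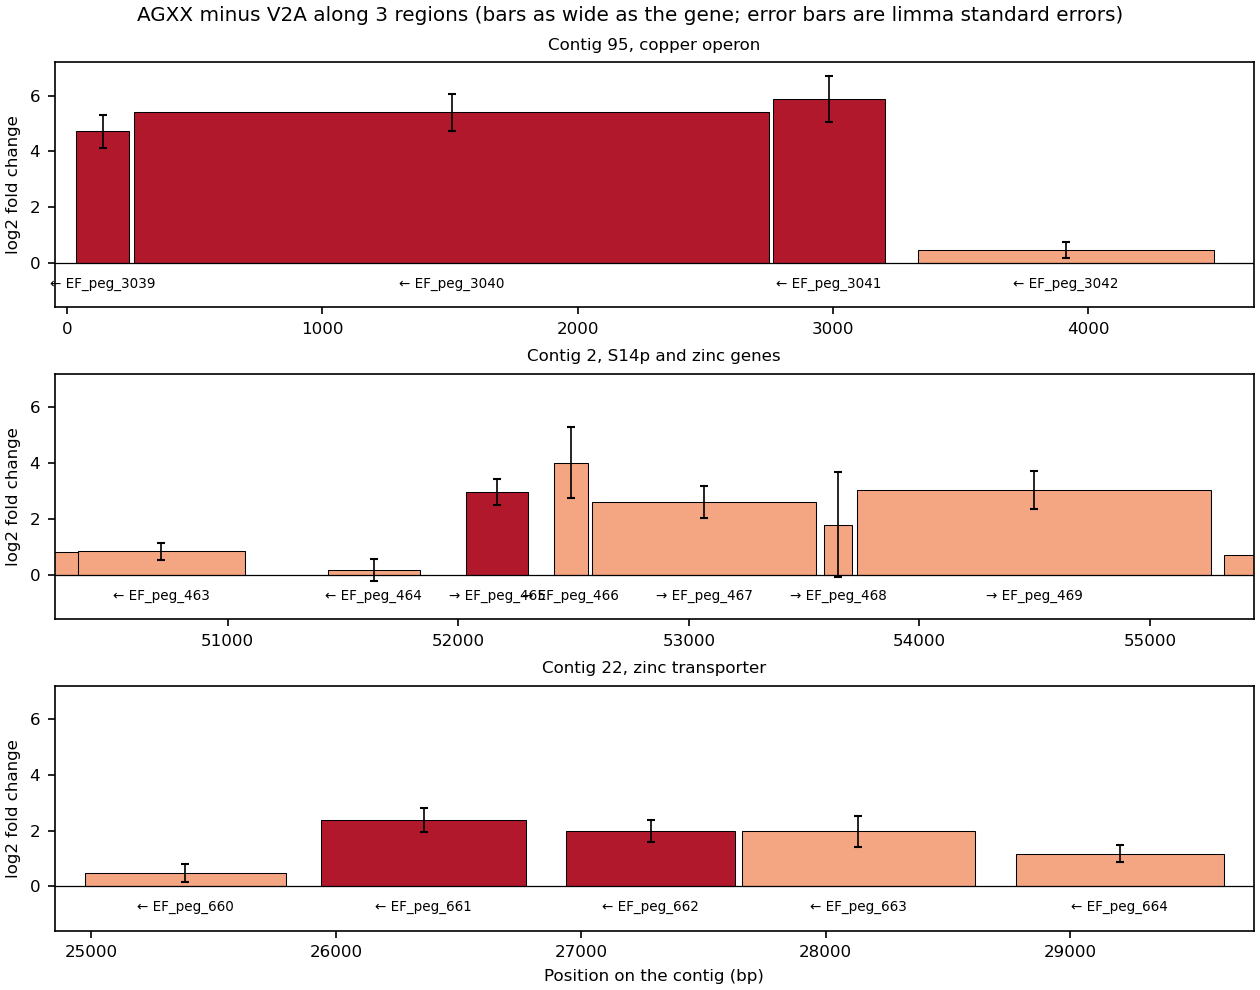
AGXX minus V2A log2 fold change (bars as wide as the gene, error bars SE, dark bars with adjusted p under 0.05) against position in bp on 3 contigs. The copper unit stands at 4.72 to 5.90, and EF_peg_465, EF_peg_661 and EF_peg_662 at 1.97 to 2.96.

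EF_peg_3034 and EF_peg_3033, cystathionine beta-synthase and gamma-lyase, which make cysteine from homocysteine, were higher with AGXX than with V2A by 2.10 ± 0.30 (adjusted p = 0.00432) and 1.54 ± 0.24 (adjusted p = 0.0088). EF_peg_3034 went from 498 FPKM at 3 min to 9.73 FPKM at 90 min with V2A and from 1223 to 120 FPKM with AGXX. It measured 801 and 1163 FPKM untreated, above all 6 V2A values and above the AGXX values from 24 min on. EF_peg_3033 measured 1062 and 1744 FPKM untreated, and 594.7 FPKM with AGXX and 147.5 FPKM with V2A at 90 min. In the cysteine and methionine list these 2 of 16 members were called, 4 rose when adjusted over the list alone, and 12 were positive (10 after quantile normalization). Camera called the list (median 0.40, adjusted p = 0.000408), with adjusted p = 0.607 with an estimated correlation. Serine acetyltransferase, EF_peg_671, had 1.39 ± 0.30 (adjusted p = 0.0604). Among 21 chaperone and Clp protease genes 20 were positive with a median of 0.63, 0 were called, and 4 rose when adjusted over the list alone. Their camera adjusted p was 3.05e-05, and adjusted p = 0.629 with an estimated correlation. The folding chaperones GroES (EF_peg_2290) and GroEL (EF_peg_2289) had 1.31 ± 0.35 and 0.85 ± 0.27 (adjusted p = 0.107 and 0.17), and ClpE (EF_peg_1416), the ATPase subunit of a protease, had 1.57 ± 0.46 (adjusted p = 0.138), and 0.98 without 60 min. EF_peg_1867, a transporter of the PnuC type for ribosyl nicotinamide that shares 35 bp with a neighbouring gene, was higher with AGXX than with V2A by 1.49 ± 0.28 (adjusted p = 0.0284). It measured 25.4 and 21.6 FPKM untreated. With AGXX it went from 86.2 FPKM at 3 min to 18.1 FPKM at 90 min, and with V2A from 21.1 to 12.1 FPKM.

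The ribosomal protein, fatty acid synthesis and peptidoglycan lists were called upward between AGXX and V2A by camera at the preset correlation, and not with an estimated one. Of 58 ribosomal protein genes, 56 were positive (median 0.61) and 1 was called, also when adjusted over the list alone, the S14p gene above. Camera gave an adjusted p of 1.02e-07 for this list, and adjusted p = 0.629 with an estimated correlation. L19p (EF_peg_251) had 1.09 ± 0.30 and L33p (EF_peg_113) 1.02 ± 0.29. All 16 fatty acid synthesis genes were positive (median 0.42, camera adjusted p = 0.00896), with 0 called in either way; adjusted p = 0.703 with an estimated correlation. After quantile normalization 13 of those 16 were positive and the list was no longer called (adjusted p = 0.0886). The acyl carrier protein EF_peg_1736 had 0.85 ± 0.33, the enoyl reductase EF_peg_144 0.70 ± 0.34 and the transacylase EF_peg_143 0.60 ± 0.32. In the peptidoglycan list 17 of 20 were positive (median 0.27, camera adjusted p = 0.0434), and 2 rose when adjusted over the list alone, with adjusted p = 0.685 with an estimated correlation. Its members EF_peg_260 and EF_peg_261, adjacent genes annotated as UDP-N-acetylmuramate-alanine ligase, had 1.13 ± 0.24 and 1.17 ± 0.30, and alanine racemase EF_peg_1602 had 0.71 ± 0.25.

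Camera called the arginine catabolism, sugar phosphotransferase and prophage lists downward between AGXX and V2A at the preset correlation and not with an estimated one, each with 0 genes called by limma over all genes or adjusted over the list alone. Of 7 arginine catabolism genes 6 were negative (7 after either scaling), with a median of -0.83 and a camera adjusted p of 0.00265, but adjusted p = 0.629 with an estimated correlation. Arginine deiminase EF_peg_2172 had -1.05 ± 0.47, ornithine carbamoyltransferase EF_peg_1386 -0.63 ± 0.35 and the regulator EF_peg_1456 -0.80 ± 0.34. Of 62 sugar phosphotransferase genes 38 were negative (median -0.23, camera adjusted p = 0.00428), with adjusted p = 0.629 with an estimated correlation. Among them were a beta-glucoside transporter, EF_peg_2402, at -2.06 ± 0.55 (adjusted p = 0.109), a trehalose transporter, EF_peg_2526, at -1.57 ± 0.43, and a maltose and glucose transporter, EF_peg_2458, at -1.41 ± 0.43. Prophage and mobile genes (41 tested, 24 negative, median -0.09) had a camera adjusted p of 0.0277, and adjusted p = 0.629 with an estimated correlation. This list was not called after median-ratio scaling (adjusted p = 0.0501) or quantile normalization (adjusted p = 0.0701). Phage tape measure EF_peg_1306 had -2.19 ± 0.67, the phage tail gene EF_peg_1309 -2.03 ± 0.66 (-1.44 without 90 min) and the integrase regulator EF_peg_1311 -1.85 ± 0.60.

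The other 11 lists were not called by camera in AGXX against V2A. Their adjusted p-values were 0.0543 for oxidative stress (27 genes, median 0.30, 5 genes rose when adjusted over the list alone), 0.0974 for purine synthesis, 0.31 for glycolysis and 0.587 for tRNA synthetases. ATP synthases, general stress and DNA repair each had 0.285, surface and virulence genes 0.705, and iron-sulfur cluster assembly and multidrug export 0.889. Pyrimidine synthesis had 0.99, and its median of 0.05 was positive while camera's direction was negative.

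**Figure D3:**
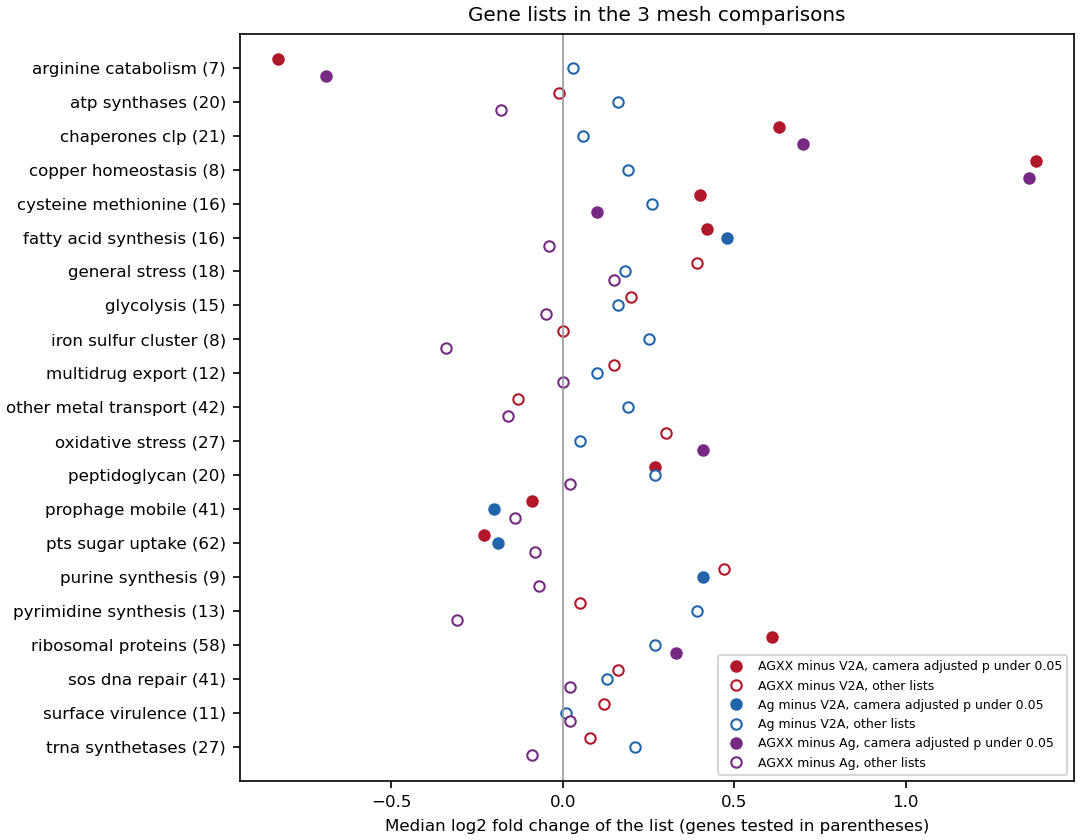
Median log2 fold change of each gene list in the 3 mesh comparisons (tested genes in parentheses), with filled points for camera adjusted p under 0.05 at the preset correlation. The copper list stands at 1.38 for AGXX minus V2A and 1.36 for AGXX minus Ag.

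In total 13 of 2534 genes were called between AGXX and V2A, all higher with AGXX, and 321 had an unadjusted p under 0.05 where chance gives 127. Besides Zur, 2 called genes lay outside the rule and were chosen after their values were seen: EF_peg_1798, a hypothetical protein (3.22 ± 0.59, adjusted p = 0.0238), and EF_peg_2384, a 117 bp gene annotated as beta-galactosidase (5.53 ± 1.09, adjusted p = 0.0367). The count moved with single times, to 6 without 6 min, 2 without 12 min, 8 without 24 or 60 min and 43 without 90 min, and with single libraries, to 8 without V2A 6 min, 7 without V2A 12 min, AGXX 6 min or AGXX 12 min, 8 without AGXX 24 min, 27 without Ag 24 min and 57 without AGXX 90 min. It was 0 with log2 depth as a covariate, which overlaps with mesh because AGXX was deeper than V2A at all 6 times. There the median SE rose from 0.33 to 0.66 and estimates moved, EF_peg_3041 from 5.90 to 4.24, EF_peg_3040 from 5.40 to 4.11, EF_peg_1929 from 1.53 to 0.85, EF_peg_1867 from 1.49 to 0.68 and EF_peg_465 from 2.96 to 3.97.

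Single times also decided several of these calls. EF_peg_3039 and EF_peg_3040 were called in each of 24 fits that left out 1 time or library. Without AGXX 90 min EF_peg_3040 stood at 6.06 and EF_peg_3041 at 6.51. EF_peg_3041 (5.82) and EF_peg_3034 (2.06) were not called without 12 min, both with an adjusted p of 0.063. EF_peg_465 was not called without 12, 24 or 60 min (2.76, 2.83 and 2.52), and EF_peg_3033 (1.48 and 1.54) and EF_peg_1929 (1.44 and 1.52) were not called without 6 or 12 min. EF_peg_661 and EF_peg_662 lost their calls without 6, 12, 24 or 60 min and without the V2A or AGXX library of any of those times, and EF_peg_662 also without Ag 6 min or Ag 12 min. In all 24 fits they stood at 2.09 to 2.81 and 1.66 to 2.36, with adjusted p up to 0.192 and 0.224. EF_peg_1867 was not called without 3, 6, 12 or 60 min, without the V2A or AGXX library of those times, or without Ag 6 min (1.35 to 1.72, adjusted p up to 0.222). In a fit of only the 12 AGXX and V2A libraries EF_peg_465 (adjusted p = 0.0944), EF_peg_661 (0.104), EF_peg_662 (0.123), EF_peg_3034 (0.0617), EF_peg_3033 (0.0511) and EF_peg_1867 (0.104) were not called, with the same fold changes. Without the time term EF_peg_3034 (0.997), EF_peg_3033 (0.464), EF_peg_1867 (0.31), EF_peg_1929 (0.114) and EF_peg_662 (0.0847) were not. EF_peg_662 was also not called without the filter on low values (0.0578) or after thinning (1.82, 0.0749).

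Plain silver was set against V2A to see what a coating without ruthenium does. The copper unit was higher with Ag than with V2A at all 6 times, without passing the test: EF_peg_3040 had 2.52 ± 0.66 (adjusted p = 0.735), EF_peg_3041 2.45 ± 0.83 and EF_peg_3039 1.75 ± 0.60 (both adjusted p = 0.954). Without Ag 90 min they stood at 1.71, 1.37 and 1.12. EF_peg_3041 differed from V2A by 1.78, 0.66, 2.89, 1.34, 0.43 and 7.60 from 3 to 90 min. The ATPase gene EF_peg_3040 measured 31.6 to 313 FPKM with Ag up to 60 min and 1157 FPKM at 90 min. Among the 8 copper genes 3 rose when adjusted over the list alone, and camera did not call the list (median 0.19, adjusted p = 0.0648). The other copper members had values between -0.18 ± 0.39 (EF_peg_2342) and 0.22 ± 0.23 (EF_peg_1929).

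Camera called 4 lists between Ag and V2A at the preset correlation, none with an estimated one, with 0 genes called in them over all genes or adjusted over the list alone. The 16 fatty acid synthesis genes were all positive (median 0.48, adjusted p = 0.00126), with adjusted p = 0.878 with an estimated correlation. EF_peg_144 had 0.70 ± 0.34, EF_peg_143 0.62 ± 0.32 and the ketoacyl synthase EF_peg_141 0.59 ± 0.34. Sugar phosphotransferase genes were called downward as a list (39 of 62 negative, median -0.19, adjusted p = 0.00019, and adjusted p = 0.817 with an estimated correlation). The trehalose transporter genes EF_peg_2526 and EF_peg_2527 had -1.11 ± 0.43 and -1.77 ± 0.97 (the latter of 135 bp, positive at 3 of 6 times, at 0 FPKM in Ag 90 min, and -0.78 without 90 min, -0.68 without Ag 90 min or -2.40 without Ag 24 min), and the maltose and glucose transporter EF_peg_2458 -0.96 ± 0.43. The prophage list was called downward too (24 of 41 negative, median -0.20, adjusted p = 0.00499, and adjusted p = 0.817 with an estimated correlation), but the members with the smallest p went both ways: a Cro-related gene, EF_peg_1052, had -2.43 ± 1.16 (-3.11 without V2A 60 min, -3.09 without V2A 6 min, -3.08 without Ag 12 min and -1.82 without V2A 90 min), a phage DNA binding gene, EF_peg_867, 1.14 ± 0.55 and a holin, EF_peg_824, 1.32 ± 0.67. All 9 purine synthesis genes were positive (median 0.41, adjusted p = 0.0475, and adjusted p = 0.817 with an estimated correlation), among them the regulator PurR (EF_peg_660, 0.54 ± 0.32), adenylosuccinate synthetase (EF_peg_2322, 0.41 ± 0.27) and inosine monophosphate dehydrogenase (EF_peg_2696, 0.54 ± 0.36).

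For single genes limma called 0 of 2534 between Ag and V2A, and 91 had an unadjusted p under 0.05 where chance gives 127. The count was 1 without V2A 24 min and 1 without Ag 3 min. The median of all genes was 0.147 higher with Ag and 0.037 after median-ratio scaling, so the list medians above stand relative to that shift.

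AGXX and Ag were compared directly to separate the 2 coatings. S14p, EF_peg_465, was higher with AGXX by 3.28 ± 0.47 (9.69-fold, adjusted p = 0.0213), the zinc importer gene ZnuC, EF_peg_662, by 2.23 ± 0.39 (adjusted p = 0.0496) and the metal ATPase EF_peg_1929 by 1.30 ± 0.23 (adjusted p = 0.0496), each at all 6 times. The copper unit was higher on average without passing the test: EF_peg_3039 had 2.98 ± 0.60 (adjusted p = 0.104), EF_peg_3040 2.88 ± 0.66 (adjusted p = 0.155) and EF_peg_3041 3.45 ± 0.83 (adjusted p = 0.198). At 90 min these 3 genes were lower with AGXX than with Ag, by a median of -2.02, against medians of 2.86 to 4.72 at the other times. Without the 90 min libraries all 3 were called: EF_peg_3041 at 4.58 (adjusted p = 8.27e-05), EF_peg_3040 at 3.86 (adjusted p = 8.27e-05) and EF_peg_3039 at 3.69 (adjusted p = 0.0023). Of the 8 copper genes 1 rose, and 5 did when adjusted over the list alone (median 1.36, 6 positive, or 7 after either scaling). The list's camera adjusted p was 6.11e-08, and adjusted p = 0.0724 with an estimated correlation. EF_peg_2342 had 1.42 ± 0.39, EF_peg_1570 0.21 ± 0.38, EF_peg_1569 -0.01 ± 0.31 and EF_peg_1517 -0.10 ± 0.20.

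Camera called the chaperone list upward between AGXX and Ag (20 of 21 positive, median 0.70, camera adjusted p = 4.13e-09, and adjusted p = 0.448 with an estimated correlation). None was called over all genes, and 3 rose when adjusted over the list alone. ClpE (EF_peg_1416) had 1.50 ± 0.46, GroES (EF_peg_2290) 1.21 ± 0.35 and GroEL (EF_peg_2289) 0.88 ± 0.27. Of 58 ribosomal protein genes 54 were positive (median 0.33, camera adjusted p = 3.79e-07, and adjusted p = 0.909 with an estimated correlation), and 1 was called both over all genes and over the list alone, S14p. The L33p genes EF_peg_113 and EF_peg_466 had 0.67 ± 0.29 and 2.42 ± 1.29, the latter 1.06 without 60 min or Ag 60 min, 1.74 without AGXX 60 min and 3.14 without Ag 90 min. Of 27 oxidative stress genes 16 were positive and 11 negative (median 0.41, camera adjusted p = 0.000731 upward, and adjusted p = 0.753 with an estimated correlation), with 0 called by limma over all genes and 2 risen when adjusted over the list alone. CoA-disulfide reductase EF_peg_1627 had 2.50 ± 0.67, the glutaredoxin-like NrdH EF_peg_2125 1.68 ± 0.44 (2.27 and called without 90 min, adjusted p = 0.00179) and thioredoxin reductase EF_peg_2875, which keeps protein thiols reduced, 0.71 ± 0.23. In the cysteine and methionine list 10 of 16 were positive (median 0.10, camera adjusted p = 0.00159, and adjusted p = 0.58 with an estimated correlation), and 6 rose when adjusted over the list alone. EF_peg_3034 had 1.33 ± 0.30, EF_peg_3033 1.15 ± 0.24 and the methionine transporter gene EF_peg_463 1.19 ± 0.31. All 7 arginine catabolism genes were negative (median -0.69, camera adjusted p = 0.00611, and adjusted p = 0.753 with an estimated correlation), among them EF_peg_2172 at -1.19 ± 0.47, EF_peg_2173 at -1.05 ± 0.59 and EF_peg_1456 at -0.62 ± 0.34. The 60 min pair weighed on 2 of these, EF_peg_2172 (-3.80 at 60 min, -0.67 without it) and EF_peg_2173 (-4.02 at 60 min, -0.45 without it, -0.37 without Ag 60 min), and EF_peg_2173 was positive at 3 and 12 min.

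Between AGXX and Ag 4 genes were called, all higher with AGXX, and 173 had an unadjusted p under 0.05; the fourth, EF_peg_24, a hypothetical protein outside the rule and chosen after its value was seen, had 1.59 ± 0.28 (adjusted p = 0.0496). The count was 48 without 90 min, 22 without AGXX 90 min and 21 without Ag 90 min, 2 without 3 min, AGXX 60 min, V2A 60 min or Ag 3 min, and 1 without 6 min, AGXX 6 min or the V2A library of 3, 6, 12 or 24 min. It was 0 without 12, 24 or 60 min, V2A 90 min, AGXX 12 or 24 min, or the Ag library of 6, 12, 24 or 60 min. EF_peg_465 was not called in 10 of the 24 such fits (those without 12, 24 or 60 min, V2A 90 min, AGXX 12 or 24 min, or Ag 6, 12, 24 or 60 min), EF_peg_662 in 20 (all but 90 min and the Ag 90 min, AGXX 3 min and AGXX 90 min libraries) and EF_peg_1929 in 21 (all but 90 min and the Ag and AGXX libraries of 90 min). Their values were 2.95 to 3.72, 1.99 to 2.59 and 1.12 to 1.49. In a fit of only the 12 AGXX and Ag libraries the 3 genes were not called (adjusted p = 0.169, 0.27 and 0.427), nor with log2 depth as a covariate (0.367, 0.999 and 0.999), where EF_peg_465 stood at 4.00. EF_peg_662 and EF_peg_1929 also lost their calls with a pseudocount of 0.1 (0.0549 and 0.0551) or 10 (both 0.0532), without the filter on low values (0.0795 and 0.0903), without the time term (0.0915 and 0.337) and after thinning (0.0729 and 0.114), and EF_peg_1929 at 20 FPKM (0.0617) and with robust moderation (0.055).

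Counts of genes at least 4-fold apart, which carry no test, show how the gap between AGXX and V2A ran over time. They were 146 at 3 min, 171 at 6 min, 210 at 12 min, 136 at 24 min, 370 at 60 min and 263 at 90 min of 2534 genes, against 179 between the 2 untreated libraries. At 60 min 296 of the 370 were higher with AGXX, and at 90 min 173 of the 263 were lower. The values were not rescaled, and these directions ran with shifts of whole libraries. The median FPKM was 33.5 with AGXX and 21.3 with V2A at 60 min, and 23.3 and 30.3 at 90 min. Ag minus V2A also had its highest count at 60 min, with 261 genes, 182 of them higher with Ag. Both counts share the 1 V2A library of 60 min, so they do not show whether the peak came from the coatings. AGXX minus Ag, which leaves that library out, had 354 genes at 60 min and 357 at 90 min. Among 1880 genes of at least 300 bp and 20 reads on average the counts between AGXX and V2A were 31, 56, 92, 34, 234 and 105, and 38 between the untreated libraries. By single time, ribosomal protein L16p, EF_peg_1132, differed by 0.01 at 3 min, -0.50 at 6 min, 3.72 at 60 min and 2.85 at 90 min. The phage gene EF_peg_1306 differed by -4.61 at 60 min and -5.01 at 90 min.

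**Figure D4:**
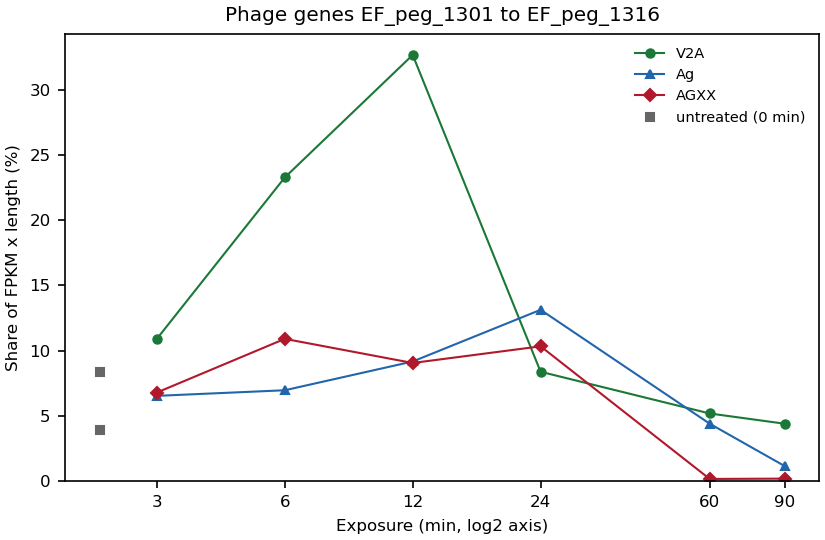
Share of FPKM times length (%) taken by the 16 phage genes EF_peg_1301 to EF_peg_1316, a block chosen after its values were seen, against exposure time (min, log2 axis), with 1 point per library and the untreated libraries as squares. The share reaches 32.7% with V2A at 12 min and is 0.145% with AGXX at 60 min.

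The slope test asked whether the AGXX difference grew or faded, and ribosomal protein genes stood out as a list. Relative to V2A, 54 of 58 had a positive slope with AGXX (median 0.45 per doubling of time, camera adjusted p = 3.4e-15, and adjusted p = 0.713 with an estimated correlation). Positive slopes also prevailed in fatty acid synthesis (14 of 16, median 0.28, adjusted p = 0.00116) and ATP synthases (17 of 20, median 0.22, adjusted p = 0.0015), each with adjusted p = 0.713 with an estimated correlation. Negative slopes prevailed in prophage genes (32 of 41, median -0.16, adjusted p = 0.00589), general stress (14 of 18, median -0.20, adjusted p = 0.00686) and oxidative stress (22 of 27, median -0.16, adjusted p = 0.0133, 2 genes adjusted over the list alone), with adjusted p = 0.713, 0.713 and 0.742 with an estimated correlation. Limma called 0 single genes for the AGXX slope, with 308 at an unadjusted p under 0.05, and 2 without 90 min. For the Ag slope it called 0, with 113 at an unadjusted p under 0.05, and camera called 0 lists, the lowest adjusted p being 0.0566 for arginine catabolism (2 of 7 genes rose when adjusted over the list alone).

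On uncoated V2A the ribosomal protein genes fell over the incubation: 34 of 58 fell and 1 rose, or 43 and 2 when adjusted over the list alone. Their median slope was -0.75 per doubling of time (n = 6 libraries, camera adjusted p = 1.05e-15, and adjusted p = 0.759 with an estimated correlation). L16p (EF_peg_1132) fell by 1.27 ± 0.15 per doubling, L18p (EF_peg_1141) fell by 1.22 ± 0.16 and L6p (EF_peg_1140) fell by 1.14 ± 0.14 (each adjusted p = 0.0252). L25p, EF_peg_540, was the exception at 1.47 ± 0.20 (adjusted p = 0.0252). Pyrimidine synthesis genes fell as well, 8 of 13 called and 10 adjusted over the list alone (median -0.69, camera adjusted p = 1.47e-05, and adjusted p = 0.759 with an estimated correlation). The mannose transporter genes EF_peg_2314 and EF_peg_2316 fell by 1.22 ± 0.27 (adjusted p = 0.0466) and fell by 1.21 ± 0.24 (adjusted p = 0.0405). Sucrose transporter EF_peg_2368 rose by 1.28 ± 0.20 (adjusted p = 0.0281), its neighbour EF_peg_2367, a glycosyl hydrolase, by 1.14 ± 0.16, the putative lipoprotein EF_peg_2375 by 1.29 ± 0.14 (both adjusted p = 0.0252) and EF_peg_2549, a 141 bp gene annotated as BacA, by 1.54 ± 0.30 (adjusted p = 0.0365). That gene stood at 0 FPKM in V2A at 3, 6 and 12 min, and its slope was 2.38 with a pseudocount of 0.1 and 0.74 with 10.

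Further lists called for time on V2A were fatty acid synthesis (3 of 16 fell, 9 adjusted over the list alone, median -0.40, camera adjusted p = 0.00333), purine synthesis (1 of 9 fell, 3 adjusted over the list alone, 0.0402) and tRNA synthetases (23 of 27 negative, 0.0284, although the 1 gene called rose). Called upward were general stress (2 of 18 rose, 3 over the list alone, 0.0168), arginine catabolism (1 of 7, 2 over the list alone, 0.0265), chaperones (1 of 21, 0.0288) and oxidative stress (3 of 27, 7 over the list alone, 0.0402). With an estimated correlation each of these had adjusted p = 0.759, and tRNA synthetases 0.76. Chaperones (adjusted p = 0.0639), oxidative stress (0.0639) and purine synthesis (0.0598) were not called after quantile normalization. In all 186 genes changed with time on V2A, 77 upward and 109 downward, with 782 at an unadjusted p under 0.05. The count rested on each single library: it was 0 without V2A 3, 6, 60 or 90 min, 35 without V2A 12 min, 132 without V2A 24 min, and 0 with minutes in place of log2(minutes). The genes named here were not called in those 5 fits with 0 calls, and EF_peg_2314 was not called with a pseudocount of 0.1 (adjusted p = 0.0519) or without the filter on low values (adjusted p = 0.0539). Further losses came without single libraries: without V2A 12 min EF_peg_2549 (1.46), EF_peg_2368 (1.31) and EF_peg_2314 (-1.15) also were not, and without V2A 24 min EF_peg_2314 (-1.22) and EF_peg_2316 (-1.21).

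Against the 2 untreated libraries camera called 10 lists for each mesh at the preset correlation, where exposure and incubation time cannot be separated. With an estimated correlation only the copper list for AGXX held (adjusted p = 0.00797), and the other calls had adjusted p = 0.52 to 0.683 for V2A, 0.612 to 0.675 for Ag and 0.27 to 0.726 for AGXX. The median of all genes was -0.29 for V2A, -0.177 for Ag and -0.244 for AGXX, and -0.004, 0.005 and -0.011 after median-ratio scaling, so the list medians below stand relative to those shifts. Ribosomal protein genes had medians of -1.96 with V2A, -1.69 with Ag and -1.38 with AGXX (55, 54 and 53 of 58 negative; camera adjusted p = 3.08e-06, 6.97e-07 and 0.00387). Fatty acid synthesis had -1.59, -1.06 and -1.07, peptidoglycan -1.02, -0.81 and -0.82, glycolysis -1.30, -1.19 and -0.99, and tRNA synthetases -0.97, -0.79 and -0.81, each called by camera with adjusted p from 0.000281 to 0.0206. Purine synthesis was called with V2A (median -1.28, adjusted p = 0.0423). Called upward were arginine catabolism (3.05, 3.09 and 2.21), chaperones (0.87, 0.85 and 1.56), oxidative stress (0.55, 0.35 and 0.74) and sugar phosphotransferases (0.74, 0.51 and 0.26), with camera adjusted p from 2.81e-07 to 0.0411. The copper list was called with Ag (median 1.44, adjusted p = 0.00803) and with AGXX (median 1.89, adjusted p = 2.79e-07).

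Over the lists alone, 5 of the 8 copper genes, 6 of 21 chaperones and 6 of 27 oxidative stress genes rose with AGXX and 1 copper gene with Ag; in the other lists called, 0 genes passed. After quantile normalization glycolysis was no longer called for V2A, Ag or AGXX (adjusted p = 0.087, 0.0614 and 0.053), nor sugar phosphotransferases (0.0619) and arginine catabolism (0.0973) for AGXX, the latter not after median-ratio scaling either (0.0951). Some splits moved with the scaling: oxidative stress genes were positive in 17 of 27 with V2A and 19 with AGXX as deposited, and in 20 and 22 after median-ratio scaling; glycolysis was negative in 14 of 15 with V2A or Ag and in 12 after either scaling. After quantile normalization 14 of 16 fatty acid genes and 22 of 27 tRNA synthetases were negative with Ag, where 16 and 25 had been, and with V2A 9 of 9 purine genes, where 8 had been. Arginine catabolism was positive in 6 of 7 with Ag, and in 7 after median-ratio scaling.

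Single genes were few: limma called 1 gene for each mesh, with 462, 267 and 300 genes at an unadjusted p under 0.05 for V2A, Ag and AGXX. With AGXX it was the copper ATPase EF_peg_3040, higher than untreated by 6.09 ± 0.99 (67.9-fold, adjusted p = 0.0172). With V2A and Ag it was EF_peg_992, a hypothetical protein outside the rule and chosen after its values were seen (4.71 ± 0.82 and 4.82 ± 0.82, adjusted p = 0.0365 and 0.0271). The counts were 4, 5 and 4 without untreated library 1 and 0 each without untreated library 2. EF_peg_3040 itself was not called without the first (6.27, adjusted p = 0.0847) or the second (5.90, adjusted p = 0.465).

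Across libraries, exposure time and mesh both showed in the main axes of variation. The first 3 principal components held 31.0%, 13.6% and 8.6% of the variance. On component 3 the AGXX libraries from 3 to 60 min lay between -22.9 and -14.0, and the V2A libraries between -5.2 and 16.2. At 90 min the order of the coatings was the other way, with AGXX at 8.8 and Ag at -38.3, where the other Ag libraries lay between 1.1 and 34.1. The 2 untreated libraries had a Pearson correlation of 0.88 across genes, and libraries of the same time on different meshes 0.78 to 0.91 (18 pairs), where genes are not independent replicates. The most abundant gene was EF_peg_2828, the DNA-binding protein HBsu, in most libraries, with 3.4% of reads in AGXX 12 min and 11.7% in AGXX 90 min.

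**Figure D5:**
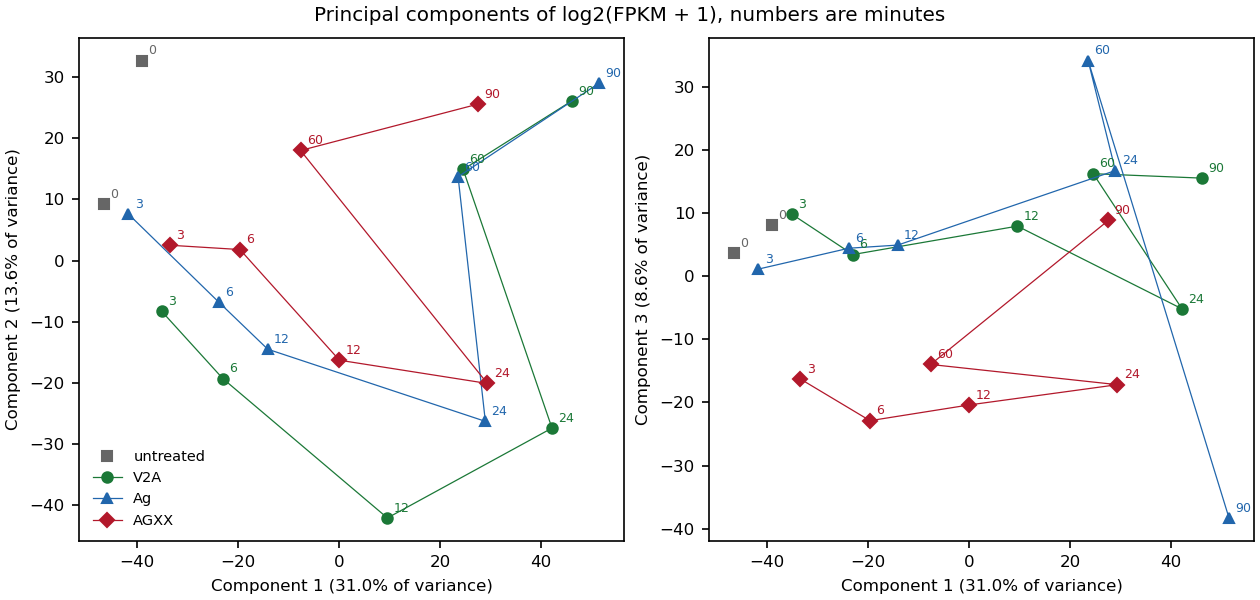
Libraries on principal components 1 and 2 (left) and 1 and 3 (right) of log2(FPKM + 1), with lines joining the times of each mesh and numbers giving minutes. On component 3 Ag 90 min lies at -38.3 and AGXX 90 min at 8.8, with the AGXX libraries from 3 to 60 min between -22.9 and -14.0.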

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

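The search for near-identical copies, the test for exchanged labels at 90 min, the swaps of labels within times, the relaxed search for a copper-repressor site, thinning and the depth covariate were tests chosen after the results had been seen. In 88 groups of 6 libraries or 6 differences, 8 had 1 value far from the rest, where chance gives about 1 in 20.

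Copper export genes with AGXX. EF_peg_3039, EF_peg_3040 and EF_peg_3041 were higher than with V2A by 4.72 to 5.90. In 32 swaps of AGXX and V2A labels within times 1, the real labelling, gave as many as 13 called genes (highest other 0). That is the lowest share 32 swaps can give, and the swaps treat the times as independent. Chance is therefore less likely for that count but not excluded. With all libraries thinned to the shallowest the 3 genes averaged 5.36 (SE 0.61 to 0.82). Thinning leaves the expected FPKM unchanged by construction. It therefore speaks only to sampling noise at low reads, and not to other causes that go with deeper AGXX libraries. With log2 depth as a covariate the 3 genes stood at 4.11 to 4.27, with SE of 1.25 to 1.66 in place of 0.60 to 0.83. The calls ended as the estimates fell and the SE rose, with depth and mesh overlapping. Reads shared with a copy are argued against, since 0 of the 3 genes have a near-identical copy. The hypothesis of an exact repressor site (TACANNTGTA, the cop box known from related bacteria) failed its test: 0.262% of 3053 genes have one, and EF_peg_3041, the first gene of the unit, has none; with 1 mismatch allowed it has TACGTTTGTA 50 bp upstream. Such relaxed sites stood upstream of 8.94% of all genes, and of 6 of 13 called genes against 209 of 2509 other tested genes (Fisher's exact test, two-sided, p = 0.000369). The 6 include EF_peg_3040 but also EF_peg_661, EF_peg_662, EF_peg_1798 and EF_peg_3033, which are not copper genes by annotation, and genes of 1 unit are not independent. The 200 bp searched before EF_peg_3040, EF_peg_662 and EF_peg_3033 lie mostly within the neighbouring genes EF_peg_3041, EF_peg_663 and EF_peg_3034. Whether sites there belong to a promoter was not tested. A response of the copper regulator to metal from the coating may explain the pattern, and which metal ion reached the cells was not tested.

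Zinc-related genes with AGXX. The 8 zinc-related genes, a set put together after their values were seen (EF_peg_465, EF_peg_466, EF_peg_467, EF_peg_469, EF_peg_661, EF_peg_662, EF_peg_663 and EF_peg_2054), had mean differences of 1.97 to 4.02 from V2A, and 4 of the 8 were called. Their median difference was 0.69 at 3 min, 3.89 at 60 min and 1.65 at 90 min. Not called were EF_peg_466, EF_peg_467, EF_peg_469 and EF_peg_663 (adjusted p = 0.17, 0.0604, 0.0704 and 0.122), and the 4.02 ± 1.29 of EF_peg_466 rests on 3 V2A libraries at 0. The 8 genes averaged 2.72 after thinning, which speaks only to sampling noise at low reads, as for the copper genes. With log2 depth as a covariate they stood at 1.43 (EF_peg_466) to 3.97 (EF_peg_465), with SE of 0.82 to 2.57. They were not called there, and depth and mesh overlap, so deeper AGXX libraries are not excluded. A site like that of the zinc repressor Zur (TCGTAATNATTACGA, up to 2 mismatches) stood upstream of 2 of 13 called genes against 9 of 2509 other tested genes (Fisher's exact test, two-sided, p = 0.00131). The sites were TCGTAACCATTACGA before EF_peg_465 and TCGTAATGATTCTGA before EF_peg_2054, with TCGTAAATATTACGG before EF_peg_663, the first gene of the importer unit. That test was aimed at zinc genes already seen among the same called genes and rests on 2 of them, so it is not independent support. Such sites are part of the genome and do not show whether repression was lost in these cultures. Loss of Zur repression is a candidate explanation that was not tested, and whether the coating lowered the zinc in the cells stays open.

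AGXX and Ag at 90 min. EF_peg_3040 and EF_peg_3041 were lower with AGXX than with Ag by -2.02 and -2.20 at 90 min, where at other times the nearest values were 2.86 and 3.41, and NrdH (EF_peg_2125) was at -1.32 (nearest 1.73). Shallow libraries as the whole cause are argued against: across 1080 genes with at least 50 reads in both libraries the 90 min difference had a correlation of -0.29 with the mean of the other times, against 0.21 to 0.60 at each other time (genes are not independent replicates). Of 48 genes called without 90 min, 41 had the opposite sign at 90 min, which goes with exchanged Ag and AGXX labels. They include the zinc importer gene EF_peg_663 at -1.49, but in the same importer EF_peg_661 was at -0.11 and EF_peg_662 at 0.58. The order of both libraries on component 3 was also reversed (Ag at -38.3, AGXX at 8.8). Ag 90 min lay beyond the AGXX libraries from 3 to 60 min, however (-22.9 to -14.0). Against an exchange stands a zinc unit of 4 genes (EF_peg_465, EF_peg_466, EF_peg_467 and EF_peg_469). Its mean was 2.51 (SD 1.94), with 3 of the genes higher with AGXX and EF_peg_466 at -0.34. The cystathionine genes EF_peg_3033 (2.45) and EF_peg_3034 (2.03) also kept their sign, and the 16 phage genes kept a low share with AGXX (0.145% at 60 min, 0.169% at 90 min, against 4.38% and 1.14% with Ag; median differences -4.36 and -2.76). The prediction for exchanged labels asked for mostly opposite signs and no positive mean in the zinc unit, so it was met only in part. AGXX 90 min was also unlike the other AGXX libraries: EF_peg_3040 was lowest there (285 FPKM), and 243 genes stood at 0 (nearest 80). An exchange of labels, a late response to silver and a change particular to AGXX 90 min therefore cannot be told apart. Each mesh has 1 library at 90 min. In 32 swaps of labels within times 2 gave at least the 4 genes called between AGXX and Ag, so chance cannot be excluded for that count; the other, which exchanges only the 90 min labels, called 63, which points to a structure of the samples at 90 min.

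The regulator of copper transport, EF_peg_3041, was 7.60 higher with Ag than with V2A at 90 min, with 2.89 as the nearest other time. EF_peg_1456, a regulator linked to agmatine use, differed by -2.82 between AGXX and V2A at 90 min, with -0.76 as the nearest. The L33p gene EF_peg_466, of 150 bp, was 9.21 higher with AGXX than with Ag at 60 min (nearest 2.24), where the Ag library stood at 0. V2A 90 min had an inferred depth of 1720000 reads (nearest V2A library 2840000). AGXX 90 min had 243 genes at 0 (nearest AGXX library 80). For the 0 genes called by limma between Ag and V2A, and for either slope, all 32 swaps necessarily give at least 0 (highest other 1, 0 and 0), so the swaps say nothing about these counts.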

How the results depend on the processing

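Chosen after seeing the data were the filter of at least 300 bp and 20 reads on average, library weights, log2 depth as a covariate and thinning. Over 90 pairs of a named gene and a comparison, 3068 values under an alternative gave 0 reversed, 199 weaker, 42 stronger, 44 moved and 2783 the same. A mean near 0, such as the 0.04 of EF_peg_1570 between AGXX and V2A, could change sign without counting as reversed. Robust moderation and the fits of 12 libraries cannot change a fold change, so the 2783 do not measure how firm the calls were. In the counts below limma called the genes, and where no cause is named the cause was not tested. Each mesh and time has 1 library, so a lone sample is assumed to vary like the others. Depth limits short genes (541 are under 300 bp) and the shallow libraries: the inferred depth was 1700000 reads in an untreated library, and at 90 min 1720000 with V2A, 1940000 with Ag and 2460000 with AGXX, against 7950000 with AGXX at 60 min. A log2 change of 1 was recovered for 34.4% of simulated genes, so limma's count of 0 between Ag and V2A leaves room for changes of that size.

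The count of 13 between AGXX and V2A became 22 with median-ratio scaling and 23 with quantile normalization (13 shared in both), and 21 of each were higher. It was 7 at a threshold of 0.01, 5 without the time term and 6 in the 12 libraries of the 2 meshes (4 shared). It was 33 (9 shared) with genes of at least 300 bp and 20 reads, which tests fewer genes, 78 with weighted libraries (61 higher, 17 lower, 13 shared) and 0 by limma with log2 depth as a covariate, where depth and mesh overlap. Leave-one-out fits gave 2 to 57. It stayed within 1.5 times of 13, at 11 to 15, with other pseudocounts, other FPKM filters, robust moderation, a 2-fold limit and thinning.

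Between AGXX and Ag 4 became 1 with a pseudocount of 0.1 or 10, without the filter, without the time term and after thinning, and 149 with weighted libraries (121 higher, 28 lower, 4 shared). Limma called 0 at a threshold of 0.01, in the 12 libraries of the 2 meshes and with log2 depth. Leave-one-out fits gave 0 to 48. Between Ag and V2A limma called 0 under all alternatives except leave-one-out fits (0 to 1). For the AGXX slope leave-one-out fits gave 0 to 2, and all other values for either slope were 0 by limma.

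Time on V2A, with 186 genes, gave 360 with median-ratio scaling and 335 with quantile normalization (185 shared in both), 331 (152 shared) with genes of at least 300 bp and 20 reads, and 0 by limma at a threshold of 0.01 or with minutes in place of log2(minutes). Leave-one-out fits gave 0 to 132.

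Against the untreated libraries each mesh had 1 gene. With V2A and with Ag limma called 0 with a pseudocount of 10, with either scaling, at a threshold of 0.01, with genes of at least 300 bp and 20 reads and after thinning, and with V2A also 0 without the filter. With AGXX the count was 2 with a pseudocount of 0.1 and with median-ratio scaling, 4 at 20 FPKM, and 0 by limma at a threshold of 0.01. In the 3 and 6 min libraries alone it was 7 for V2A, 6 for Ag and 18 for AGXX (1 shared each). Leave-one-out fits gave 0 to 4 for V2A, 0 to 5 for Ag and 0 to 4 for AGXX.

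Genes at least 4-fold apart between AGXX and V2A from 3 to 90 min (146, 171, 210, 136, 370 and 263) were 66, 84, 119, 67, 231 and 149 with a pseudocount of 10, which shrinks low values by construction. At least 2-fold apart were 390, 568, 660, 445, 1108 and 840. With genes of at least 300 bp and 20 reads they were 31, 56, 92, 34, 234 and 105.

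The gene lists called by camera numbered 9 for AGXX against V2A, 4 for Ag against V2A, 6 for AGXX against Ag, 6 for the AGXX slope, 9 for time on V2A and 10 for each mesh against untreated. With an estimated correlation 0 were called in each, apart from 1 for AGXX against untreated, the copper list. With genes of at least 300 bp and 20 reads 1 was called for the Ag slope, where 0 had been, and 5 for time on V2A.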

Other observations

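The gene groups and genes here were chosen after their values were seen, and none of their members was called by limma in the main fit of the 3 meshes. A block of 16 phage genes on contig 35 (24152 to 37557, EF_peg_1301 to EF_peg_1316) took a large and changing share of the reads. Its share of FPKM times length was 8.37% and 3.91% in the untreated libraries. With V2A it ran from 10.9% at 3 min through 23.3% and 32.7% at 6 and 12 min to 8.37%, 5.17% and 4.38% at 24, 60 and 90 min. With AGXX it was 6.78% to 10.9% up to 24 min, then 0.145% at 60 min and 0.169% at 90 min, and with Ag it was 13.1% at 24 min and 1.14% at 90 min. At 60 and 90 min the median difference between AGXX and V2A over the block was -4.22 and -4.82, against 0.05 and -0.45 for 20 flanking genes. Over all times the adjusted p-values of the 16 genes lay between 0.152 and 0.484.

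Other groups differed between AGXX and V2A in their means over the 6 times. A sulfur transfer unit on contig 4 (EF_peg_1626 to EF_peg_1629, with a rhodanese-like protein and CoA-disulfide reductase) had a median of 2.67 and adjusted p-values of 0.0894 to 0.114. Without the 90 min libraries limma called EF_peg_1628 (2.73, adjusted p = 0.0257) and EF_peg_1629 (2.14, adjusted p = 0.0449) higher with AGXX than with Ag. At 90 min they differed by -2.19 and 0.17. The rhodanese-like gene EF_peg_1626 measured 30.0 FPKM with V2A and 4717 FPKM with AGXX at 60 min. It measured 14.5 and 21.3 FPKM at 3 min, and 57.8 and 294 FPKM at 90 min. The class Ib ribonucleotide reductase genes EF_peg_2125 to EF_peg_2129, which make deoxyribonucleotides, had a median of 1.33 (adjusted p = 0.0704 to 0.109). At 90 min alone their median difference was -0.27. Lower with AGXX were 6 maltose uptake and use genes (median -1.84, adjusted p = 0.0604 to 0.149) and 5 galactose genes (median -1.35, adjusted p = 0.0704 to 0.0995). Both groups also had negative medians for Ag minus V2A, at -1.16 and -0.76. Between AGXX and Ag their medians were -0.58 and -0.61. The maltose binding protein gene EF_peg_1997 measured 3.9 and 2.6 FPKM untreated, and 456 FPKM with V2A, 302 FPKM with Ag and 169 FPKM with AGXX at 12 min, but 536, 726 and 219 FPKM at 24 min. Galactokinase, EF_peg_625, measured 280 FPKM with V2A, 57.8 FPKM with Ag and 30.7 FPKM with AGXX at 12 min, but 291, 420 and 149 FPKM at 24 min. At 24 min the median difference between Ag and V2A was 0.64 for the maltose and 0.46 for the galactose genes, against -0.63 and -2.29 at 12 min.

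Without the 90 min libraries limma called genes of iron uptake and fermentation lower with AGXX than with Ag. The iron compound importer genes EF_peg_1714 to EF_peg_1718 had -1.33 to -2.46 (adjusted p = 0.00669 to 0.0261), the ferrous iron transporter EF_peg_2122 -1.66 ± 0.32 and pyruvate formate-lyase EF_peg_2354 -2.60 ± 0.49 (adjusted p = 0.0257). At 90 min the same genes were higher with AGXX, EF_peg_1714 to EF_peg_1718 by 1.62 to 2.84 and EF_peg_2354 by 3.57. Library weights estimated from the spread were lowest for AGXX 90 min (0.24), Ag 90 min (0.26) and V2A 60 min (0.26). Of 539 genes under the filter on low values, 0 lay above all V2A and untreated libraries in every AGXX library.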
